A study of Andropogon gerardi with 36 samples.

How the data were processed

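RNA of big bluestem (Andropogon gerardi), a prairie grass, was compared on spotted arrays made for maize. Per the labels, total RNA was extracted with an RNeasy kit, labelled with a Genisphere array kit, and hybridised with 1 sample in the Cy5 channel and another in the Cy3 channel of each array. The label of each channel gives a plot, a subplot digit, a letter and a month. The 12 plots were always met in the same 6 pairs, and subplot 1 was always set against subplot 1, or subplots 2 and 4 against 2 and 4. Which plots had altered soil moisture and which subplots were warmed is not given in the sources used here, so the groups are plot pairs, sampling times and subplots.

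The deposited values were log10 of a ratio within each array, which was settled from the values. Between 82.3% and 99.1% of the values of an array were log10 of a ratio of whole numbers with a denominator up to 1000, within a tolerance of 6e-10. After a small shift of the same values that share was at most 0.129%. Scanner, image software, background correction, normalization and filters are not given in the sources used here, and neither is the direction of the ratio (Cy5 over Cy3 or the reverse). All values were converted to log2 here. Of the 36 arrays, 1 was not used because its column was empty, and 1 was labelled with the same plant code in both channels and stayed outside the comparisons, which left 34. The median of these 34 arrays lay between -0.11 and 0.12 on the log2 scale, and that of the array with 1 plant code was -0.40.

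Of 19200 probes, 1800 had 1 gene symbol in the platform's annotation, 23 had several and 17377 had none. The 1800 probes carried 583 symbols, of which 539 were locus numbers. Probes with several symbols were not named.

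The ratio of each array was turned so that the lower-numbered plot came first, which changed the sign of the 5 arrays with that plot in Cy3. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a coefficient for each pair, a dye term, and a random block for arrays of the same pair and subplots (duplicateCorrelation with statmod 1.5.0). Probes with values on at least 28 arrays and on at least 2 arrays of each pair entered, 1668 in all. Changes of the plot difference between times and between subplots were tested with cell means for each pair and time or each pair and subplot, where all coefficients could be estimated. F tests used the covariance of each probe's own arrays with limma's moderated variance. Because the direction of the deposited ratios is unstated, every count was also made with the ratios as deposited, with no dye term. Calls are Benjamini-Hochberg adjusted p under 0.05.

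The arrays of a pair came from different months or subplots, and many repeat a code of plot, subplot and letter. What the letter stands for is not given in the sources used here. Joined by shared codes, the arrays form 2 sets in plots 2 and 3, 4 in plots 4 and 5, 3 in plots 6 and 9, 3 in plots 7 and 10, 2 in plots 11 and 12 and 2 in plots 13 and 15. Tests over arrays take arrays with a shared code as separate, so their p-values are too small if such arrays depend on each other. Same-pair arrays with a shared code had a mean correlation of 0.0699 as deposited, and those without 0.0651. Same-pair arrays of the same sampling time had 0.116 (14 of 16 above 0), and those of different times 0.0559 (57 of 76 above 0). Neither the sign-flip tests nor the block of the pair fit allowed for a shared sampling time. For gene groups, the mean over the probes of the group was taken on each array with at least 2 measured probes. The mean over a pair's arrays was set against 0 with an exact two-sided sign-flip permutation test. Spread and number of values per array were tested with 100000 permutations, two-sided. The deposited files give no signal over background, and the number of arrays limits the precision.

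Before the data were examined, 19 gene lists were fixed as name patterns, along with the tests, the alternatives and the rule for naming genes. The sign-flip tests of gene-group means were not among those tests. Only the list of heat shock proteins and chaperones matched any annotated probe, 22 probes of the hsp70-4 and hsp70-5 genes. The other 18 lists matched none: photosystems, C4 and Calvin cycle, water deficit, aquaporins, oxidative stress, sugar and starch, cell wall, phenylpropanoids, defence, ribosomal proteins, ubiquitin and proteasome, histones and cell division, hormones, nitrogen, reference genes, seed storage, pollen and flower, and root. The groups Sod4A, TCTP, MNB1b, mbd genes, tubulin, RPL27A and opr genes were added after the annotation and the data had been seen. List tests used the preranked form of camera, since the values have gaps, with a preset correlation of 0.01 and with an estimated one. Fisher's exact test compared the share of members with an unadjusted p under 0.05 with that of other probes, two-sided, because the planned test on calls had none to count. Only locus numbers name most genes, so those are given without a function.

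The rule named, for each F test, the 10 annotated probes with the smallest p. It also named, for each pair, up to 4 probes of each sign past the threshold, and up to 4 probes of each fixed list with the smallest p over the 6 pairs. The alternatives were median centring, equal scale, stricter and looser filters, no dye term, no block, robust moderation, averaging of same-gene probes, no turning, addition of the array with 1 plant code, single seasons, and each array left out.

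The models were tested on simulated data with 200 changed probes, the measured spreads and the measured gaps. For the pair tests the change was put into 1 pair at a time. The simulated ratios followed the channel orientation, as if the deposited ratios had not yet been turned. If the deposited ratios had already been turned, the recovery would not hold for pairs run in both orientations, plots 2 and 3 and plots 7 and 10. At a log2 difference of 1, the fit recovered 93.5% of the changed probes for plots 2 and 3, 75.5% for plots 4 and 5, 75.5% for plots 6 and 9, 69.5% for plots 7 and 10, 44.0% for plots 11 and 12 and 46.5% for plots 13 and 15, over 1668 probes. The F test over the pairs recovered fewer, 75.0%, 53.0%, 56.0%, 28.0%, 13.0% and 10.5% in the same order. At 0.5, the F test recovered 0% in every pair, and the test of the pair alone recovered 33.5% for plots 2 and 3 and at most 6.00% for the others. The subplot test recovered 75.1% at 1 over 1583 probes, with the change put into the subplot 1 arrays of every pair at once. Recovery of a subplot change in a single pair was not simulated. The test over 4 times recovered 0 of 154 changed probes at 1, and the test of August against June 6.90%. For these the change was put into the August arrays of every pair tested.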

Results

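Big bluestem plants of 12 sheltered plots at Konza, in a study of warming and altered soil moisture, were compared for transcript levels on 2-colour maize arrays. Each array set RNA of 1 plot against RNA of its partner plot. The 34 arrays used here comprised 8 of plots 2 and 3, 7 of plots 4 and 5, 8 of plots 6 and 9, 4 of plots 7 and 10, 4 of plots 11 and 12, and 3 of plots 13 and 15. Sampling gave 11 arrays in June, 6 in the set named JulyA, 6 in JulyB and 11 in August. An array carried values for 2199 to 9530 probes, with a median of 5357. Ratios are log2 values with the lower-numbered plot first, taking the deposited ratio as Cy5 over Cy3, except where they are given as deposited. Since that direction is unstated, signs compare arrays with each other and do not say which plot was higher. Treatments of single plots and subplots are not given in the sources used here.

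The first question was which transcripts differed between partner plots. The hsp70 probes, for a chaperone family that binds unfolded proteins and is induced by heat in plants, had a positive mean on 7 of 7 arrays of plots 4 and 5. Their mean log2 ratio there was 0.51 ± 0.40 (SD, n = 7; exact sign-flip permutation p = 0.0156, the smallest that 7 arrays allow; adjusted p = 0.0938 over 6 pairs). The sign-flip test was not among the tests fixed beforehand. The array means ran from 0.08 on a JulyA array to 1.28 on the August array. Some of these arrays shared a plant code, and averaged over shared codes the mean was 0.42 ± 0.23, positive in 4 of 4 sets (SD, n = 4; exact p = 0.125, the smallest that 4 sets allow). In plots 6 and 9 the hsp70 mean was positive on 4 arrays and negative on 4, with a mean of 0.00 ± 0.58 (SD, n = 8). In plots 2 and 3 it was -0.17 ± 0.50 (SD, n = 8), or -0.13 ± 0.52 as deposited, and in plots 11 and 12 it was 0.26 ± 0.67 (SD, n = 4). Plots 13 and 15 gave 0.01 ± 0.07 (SD, n = 3) and plots 7 and 10 gave -0.01 ± 0.73 (SD, n = 4), or 0.37 ± 0.58 as deposited.

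The 2 genes of the family moved alike in plots 4 and 5: hsp70-4 had a mean of 0.55 ± 0.38 and hsp70-5 a mean of 0.46 ± 0.42 (SD, n = 7 each), both positive on 7 of 7 arrays. In the fit of all probes, 12 of the 13 hsp70 probes had a positive coefficient in plots 4 and 5, and camera with the preset correlation gave an adjusted p of 8.37e-06 for the list. That call was lost with an estimated correlation, where p = 0.0929 and adjusted p = 0.557, with 0.696 as the correlation between members. As deposited, camera with the preset correlation also called the list in plots 2 and 3 (adjusted p = 0.00207, mean -0.18) and in plots 7 and 10 (adjusted p = 2.35e-07, mean 0.41). With an estimated correlation these were lost too (adjusted p = 0.507 and adjusted p = 0.183). With turned ratios no list member passed the threshold for plot differences when adjusted over the list alone or over all probes, and as deposited 2 passed in the F test when adjusted over the list alone and 0 over all probes. The hsp70-4 probe 3325 had the largest value of the 4 probes named from the list, 0.91 ± 0.35 (SE; limma adjusted p = 0.511). The others were hsp70-4 probe 5377 at 0.65 ± 0.27, hsp70-4 probe 4164 at 0.52 ± 0.27 and hsp70-5 probe 6217 at 0.44 ± 0.30.

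**Figure D1:**
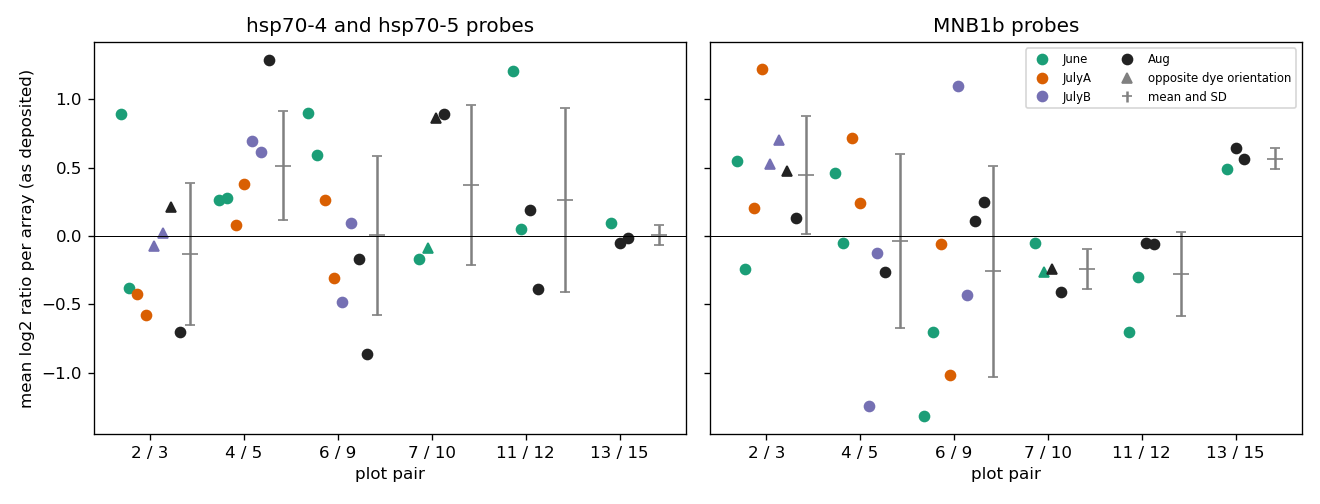
Mean log2 ratio per array, as deposited, over the hsp70-4 and hsp70-5 probes (left) and the MNB1b probes (right), by plot pair; points are arrays coloured by sampling time, triangles are arrays with the lower-numbered plot in Cy3, and bars give the mean and SD. The hsp70 means of plots 4 and 5 lay between 0.08 and 1.28, all above 0, while the MNB1b means of all pairs ran from -1.32 to 1.22.

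Other gene groups were added after the annotation and the data had been seen. The mean over probes for MNB1b, a DNA-binding protein of the HMG type, ran from -1.32 to 1.22 over the 34 arrays and exceeded 1 in size on 5 of them. TCTP, the translationally controlled tumor protein, ran from -0.63 to 1.61, and Sod4A, a superoxide dismutase that removes superoxide radicals, from -0.61 to 0.58. TCTP was negative on 7 of 8 arrays of plots 6 and 9, with a mean of -0.29 ± 0.22 (SD, n = 8; exact sign-flip permutation p = 0.0234, adjusted p = 0.562 over 36 tests). The ribosomal protein RPL27A was negative on 6 of 7 arrays of plots 4 and 5, at -0.19 ± 0.17 (SD, n = 7; exact p = 0.0469, adjusted p = 0.562). That p rose to 0.438 when only probes with values on at least 28 arrays were used, by the exact permutation test. Averaged over shared plant codes, TCTP in plots 6 and 9 was negative in 3 of 3 sets (exact p = 0.25, the smallest possible) and RPL27A in plots 4 and 5 in 4 of 4 (exact p = 0.125, the smallest possible). Probes of RPL27A did not move together across arrays (median r = -0.0653 over 5 probes), nor did the 2 of the tubulin gene tua4 (r = -0.0627). Tubulin in plots 2 and 3 gave -0.28 ± 0.29 (SD, n = 8; exact p = 0.0391, adjusted p = 0.562) with turned ratios and exact p = 0.281 as deposited. Sod4A stayed between -0.06 and 0.08 as a mean in each pair, with SDs of 0.28 to 0.52, and as deposited its mean in plots 7 and 10 was 0.22 ± 0.40 (SD, n = 4). The opr genes of oxylipin metabolism had 2 or more measured probes on 3 arrays only and were not tested.

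Over all 1668 probes, of which 433 carried a symbol, the limma fit called 0 probes in any pair, and 123 had an unadjusted p under 0.05 in the F test where chance gives 83.4. Each pair and the dye term also gave 0 calls. The 0 of plots 11 and 12 was not stable: 31 probes passed with no dye term, 29 of the 104 measured on all arrays, and 76 without its August array replicate 4. The counts at an unadjusted p under 0.05 were 76 for plots 2 and 3, 129 for plots 4 and 5, 117 for plots 6 and 9, 16 for plots 7 and 10, 135 for plots 11 and 12, 79 for plots 13 and 15 and 112 for the dye term. As deposited, with no dye term, they were 367 for the F test and, in the same order of pairs, 370, 167, 191, 85, 248 and 119. The annotated probes with the smallest F-test p were LOC542438 (probe 1765), with 1.36 ± 0.31 (SE) in plots 4 and 5 and a limma adjusted p of 0.441, and LOC542445 (probe 2842), with 0.60 ± 0.22 in plots 13 and 15. A second LOC542438 probe (470) had 1.22 ± 0.38 in plots 4 and 5, and as deposited the values of these LOC542438 probes were 0.64 ± 0.24 (probe 1765) and 0.60 ± 0.29 (probe 470). MNB1b probes 12505 and 12499 had -1.12 ± 0.29 and -0.90 ± 0.27 in plots 6 and 9, or -0.60 ± 0.20 and -0.49 ± 0.17 as deposited. Plots 4 and 5 and plots 6 and 9 had the lower-numbered plot in Cy5 on every array, so turning changed none of them. The gaps between these values come from the dye term, which is estimated from the pairs run in both orientations. In plots 11 and 12, among the LOC542458 probes, those with the smallest p had 0.94 ± 0.41 (probe 12158) and 0.69 ± 0.34 (probe 2323), LOC100037748 (probe 10170) had 0.54 ± 0.20, and RPL27A (probe 6457) had -0.67 ± 0.21. LOC541973 (probe 9449) had 0.96 ± 0.37 in plots 13 and 15. The limma adjusted p of these 10 probes ran from 0.441 to 0.603.

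With the ratios as deposited, the MNB1b mean of plots 2 and 3 was positive on 7 of 8 arrays, at 0.45 ± 0.43 (SD, n = 8; exact sign-flip permutation p = 0.0312, adjusted p = 0.375 over 36 tests), against 0.02 ± 0.64 with turned ratios. The mbd genes, for proteins with a methyl-CpG-binding domain, were negative on 7 of 8 arrays as deposited, at -0.34 ± 0.31 (SD, n = 8; exact p = 0.0312, adjusted p = 0.375), against -0.03 ± 0.48 when turned. The arrays of plots 2 and 3 form 2 sets with no plant code in common, too few for an exact p under 0.5. MNB1b had 230 of the 1800 probes with 1 gene symbol. Its probes moved together across arrays (median r = 0.804 over 60 probes), so counts of them are not counts of separate observations. The limma fit of the deposited ratios called 95 probes in plots 2 and 3, 75 positive and 20 negative, among them 22 MNB1b probes. The named probes there were MNB1b probes 7733 at 1.02 ± 0.27 (SE), 7688 at 0.96 ± 0.19, 12499 at 0.81 ± 0.17 and 10564 at 0.77 ± 0.18, and on the negative side LOC542316 (probe 2840) at -0.64 ± 0.15, with limma adjusted p from 0.0110 to 0.0240. It called 44 probes in plots 11 and 12, 12 positive and 32 negative, where LOC542458 (probe 12158) had 1.22 ± 0.34 on 3 arrays, LOC542581 (probe 2816) 0.69 ± 0.18 and RPL27A (probe 6457) -0.66 ± 0.17. It called 5 in plots 13 and 15, all without a symbol, and 0 in the remaining pairs. This fit had no dye term, so a dye effect on single probes could also give such calls. In plots 11 and 12 and plots 13 and 15, run in a single orientation, dye and plot cannot be told apart by that fit. The block correlation was -0.07, which narrows the errors. Without the block the calls fell to 11, 14 and 1, and 2 of the 22 MNB1b probes remained. The 14 of plots 11 and 12 were then all negative and had no symbol, so the probes named there lost their calls. Leaving out 1 array at a time then moved the 11 of plots 2 and 3 to between 0 and 24, with 0 for 16 of the 34 arrays, the 14 of plots 11 and 12 to between 0 and 105, and the 1 of plots 13 and 15 to between 0 and 5.

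The next question was whether the difference between partner plots changed over the season. In plots 6 and 9 the MNB1b mean was -1.32 and -0.70 on the June arrays, -0.06 and -1.02 in JulyA, 1.09 and -0.43 in JulyB and 0.11 and 0.25 in August. The hsp70 mean of the same pair was 0.90 and 0.59 in June, 0.26 and -0.31 in JulyA, -0.48 and 0.09 in JulyB and -0.17 and -0.86 in August. In plots 4 and 5 the hsp70 mean was 0.27 and 0.28 in June, 0.08 and 0.38 in JulyA, 0.69 and 0.61 in JulyB and 1.28 on the August array. These means were not tested for a change over time. Among single probes, limma called 0 of 1241 for a change over the 4 times, with 65 at an unadjusted p under 0.05, and 0 of 1194 for August against June, with 93. As deposited, it called 0 of 1368 over the 4 times, with 97 at an unadjusted p under 0.05, and 8 of 1194 for August against June, with 199, and without the block 0, with 133.

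The 10 annotated probes with the smallest p for August against June included 8 of MNB1b. That gene had 230 of the 1800 probes with 1 gene symbol, and its probes moved together across arrays, so the 8 are not separate observations. The coefficients of these 8 in plots 6 and 9 ran from 1.22 ± 0.40 (probe 5679) to 2.20 ± 0.49 (SE; probe 1374). The other 2 were LOC541649 (probe 2093), with 2.09 ± 0.56 in plots 11 and 12, and hsp70-5 (probe 9851), with -1.96 ± 0.58 there, all with a limma adjusted p of 0.604. As deposited, LOC541649 (probe 2093) passed, at 2.09 ± 0.38 and a limma adjusted p of 0.0231. Without the block, no probe passed that test as deposited. For the 4 times, LOC542725 came first, with 2.57 ± 0.54 (probe 524) in plots 6 and 9 for JulyA against June and a limma adjusted p of 0.328. Other LOC542725 probes had 1.78 ± 0.45 (probe 13699) and 2.59 ± 0.74 (probe 12128) in that pair for JulyB. MNB1b had 1.94 ± 0.56 (probe 2579) and 2.37 ± 0.67 (probe 4578) there for JulyB. The hsp70-5 probes had -1.70 ± 0.42 (probe 5655) in plots 6 and 9 and 1.57 ± 0.58 (probe 8475) in plots 4 and 5 for August. LOC541886 (probe 10426) had -2.94 ± 0.80, LOC732811 (probe 10848) 2.91 ± 1.12 and LOC542701 (probe 16844) 2.70 ± 0.76 in plots 2 and 3. For JulyB against June in that pair the values rest on the turning, since as deposited LOC541886 (probe 10426) had -0.06 ± 0.45 and LOC732811 (probe 10848) had -0.24 ± 0.64. Of the 11 hsp70 probes tested over the 4 times, 3 had an unadjusted p under 0.05, against 62 of 1230 other probes (Fisher's exact p = 0.0167), and 0 passed when adjusted over the list alone. For August against June it was 2 of 9 members (Fisher's exact p = 0.151), and for the 6 pairs 1 of 13 (Fisher's exact p = 1). As deposited, 2 of 11 hsp70 probes had an unadjusted p under 0.05 over the 4 times (Fisher's exact p = 0.180). For August against June as deposited it was 8 of 9, against 191 of 1185 others (Fisher's exact p = 4.08e-06). Of the 9, 5 passed when adjusted over the list alone and 1 over all probes. The call over all probes was lost without the block. For the 6 pairs it was 4 of 13 as deposited, against 363 of 1655 (Fisher's exact p = 0.499). These p-values are not corrected for the number of tests and take correlated probes as independent. The simulated recovery of 0 for the test over 4 times limits what its count of 0 can show.

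The number of probes with a value rose with the season, from 4248.6 ± 1763.3 (SD, n = 11) in June and 4307.8 ± 667 (n = 6) in JulyA to 5146.2 ± 1373.7 (n = 6) in JulyB and 7655.3 ± 1257.2 (n = 11) in August. A two-sided permutation test, with times permuted within pairs, gave p = 6e-05 for this difference, a test added after the data were seen. The spread of log2 ratios within an array, as the scaled median absolute deviation, did not follow: it was 0.54 ± 0.15 in June, 0.62 ± 0.12 in JulyA, 0.61 ± 0.08 in JulyB and 0.54 ± 0.07 in August (SD over arrays; permutation p = 0.443).

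**Figure D2:**
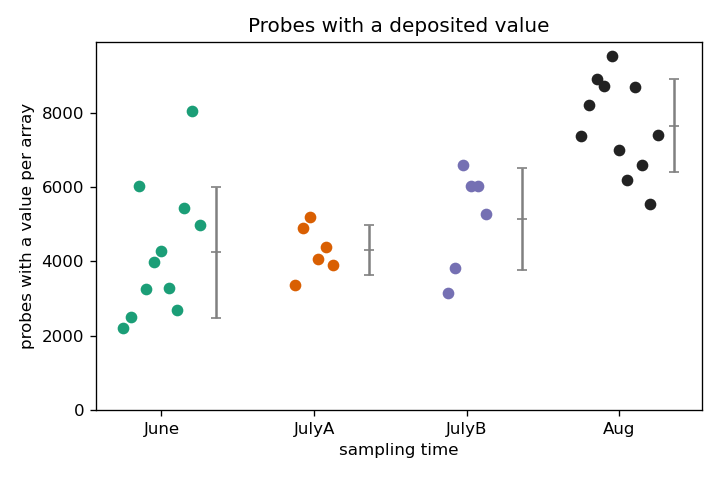
Number of probes with a deposited value on each of the 34 arrays, by sampling time; points are arrays and bars give the mean and SD. August arrays lay between 5558 and 9530 probes and June arrays between 2199 and 8038.

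The last comparison was of the plot difference between arrays of subplot 1 and arrays of the other subplots. It does not compare transcript levels between subplots of a plot, which no array set side by side. LOC542454 (probe 931) and TCTP (probe 10443) were the annotated probes with the smallest p. The plot difference on subplot 1 arrays minus that on the others was 1.61 ± 0.32 (SE) for LOC542454 in plots 6 and 9. For TCTP it was 1.07 ± 0.44 in plots 7 and 10. In plots 7 and 10, hsp70-4 (probe 7677) had -1.79 ± 0.65, hsp70-5 (probe 6217) -1.96 ± 0.65 and Sod4A (probe 10018) -1.08 ± 0.51. As deposited, these plots 7 and 10 values were -0.80 ± 0.66 for hsp70-4 (probe 7677), -0.62 ± 0.63 for hsp70-5 (probe 6217), -0.46 ± 0.49 for Sod4A (probe 10018) and -0.88 ± 0.45 for TCTP (probe 10443). In plots 11 and 12, LOC541664 (probe 13085) had 2.01 ± 0.54, LOC541662 (probe 13737) -1.81 ± 0.46, LOC542212 (probe 16448) -2.46 ± 0.84 and LOC542301 (probe 9306) 1.83 ± 0.71. LOC541886 (probe 14461) had 2.19 ± 0.95 in plots 13 and 15. None passed: limma called 0 of 1583 probes, with 40 at an unadjusted p under 0.05 and the adjusted p of each of the 10 was above 0.99. Of the 13 hsp70 probes, 2 had an unadjusted p under 0.05, against 38 of 1570 others (Fisher's exact p = 0.0407), and as deposited 0 of 13, against 50 of 1570 (Fisher's exact p = 1). The spread of ratios was 0.57 ± 0.11 on subplot 1 arrays and 0.57 ± 0.11 on their partners (SD, n = 16 combinations of pair and time; permutation p = 0.959).

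Between pairs, plot differences of the same probes were compared across probes, which are not independent. The strongest of 15 correlations was that of plots 4 and 5 with plots 6 and 9 (Pearson r = 0.562, Spearman rho = 0.543). The shared dye term alone gave 0.406 in 100 simulated data sets, and the covariance was 0.0466 against a simulated 0.0300. As deposited, with no dye term, r was 0.311. Plots 11 and 12 against plots 13 and 15 gave r = -0.177 and rho = -0.205, where the simulation gave 0.231. The mean of the 15 Pearson values was 0.103 against a simulated 0.162.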

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

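The tests of the dye orientation, of a dye effect on the hsp70 probes, of the deposited ratios and of shared plant codes were chosen after the values had been seen. The tests of signal strength and slide position were set out first.

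Of 54 groups of array means tested, 3 held an array far from the rest, and chance flags about 1 in 20. As deposited, TCTP had a mean of 1.61 on the JulyA array of plots 2 and 3 with subplots 2 and 4, against -0.57 to 0.05 on the other 7 arrays; with turned ratios the others ran from -0.52 to 0.57 and the array did not stand apart. Turned ratios instead set apart hsp70-4 on a June array of plots 2 and 3, at 1.01 against -0.73 to 0.02. Tubulin had 1.11 on a June array of plots 4 and 5, against -0.40 to 0.12 on the others, and -1.01 on a JulyB array of plots 6 and 9, against -0.17 to 0.29. The array labelled with the same plant code in both channels, which entered no comparison, had a scaled median absolute deviation of 1.33, against 0.31 to 0.81 on the 34 others.

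The first pattern weighed was that arrays of the same plots in opposite dye orientation agreed as deposited. All 19 such array pairs correlated above 0, with a mean of 0.147 across probes, and random turning of arrays gave a permutation p of 0.00188. Arrays in the same orientation had a lower mean, 0.0893 in the pairs run both ways (12 of 15 above 0, permutation p = 0.0114) and 0.0340 in the pairs run in a single orientation. A candidate explanation is that the deposited ratios had already been turned to a common plot direction, in which case turning them again cancels the plot difference. A dye effect shared by all arrays was argued against by an exchange of arrays between pairs within an orientation, which gave a mean of 0.0495, with 95% of exchanges between 0.0057 and 0.0933 (one-sided permutation p = 4e-05). Arrays of different pairs had a mean correlation of 0.0297. A dye effect peculiar to certain plots stays open. A biological difference between plots 2 and 3 that kept its direction over time would change sign with the orientation. So would an effect of plants shared between arrays. Either could give this agreement only if the deposited ratios had already been turned. A plot difference that reversed between sampling times stays open, because orientation was tied to time. In plots 2 and 3 the June and JulyA arrays had plot 2 in Cy5, the JulyB arrays had plot 3 in Cy5, and only August had both. Whether a biological difference between these plots exists also stays open, since treatments are not assigned here. Dependence between arrays with a shared plant code limits the p-values.

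The second pattern was the positive hsp70 mean on all arrays of plots 4 and 5. A dye effect on these probes was argued against by the other pairs hybridised in a single orientation, where 7 of 15 arrays had a negative hsp70 mean. Signal strength was approximated from the whole numbers of each ratio in lowest terms, which lose any common factor. Removal of the trend with this stand-in left 84.3% of the mean, at 0.44 ± 0.41 with 6 of 7 arrays positive. Before removal it was 0.52 ± 0.41 on the same probes. The stand-in cannot decide whether a trend with the true signal strength contributes. Chance stays open after correction over the 6 pairs and with arrays of a shared plant code averaged, at 0.42 and exact p = 0.125, and a difference in growing conditions between plots 4 and 5 may contribute but was not tested.

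The third pattern was that probes of a gene moved together on an array, while arrays of the same plots correlated weakly, with a mean of 0.0454 in the same orientation. Over 72 genes with several probes, the median correlation of same-gene probes across arrays was 0.563, against 0.0022 for 3000 random probe pairs, and 55 genes lay over 0.3. For hsp70-5 it was 0.881, for hsp70-4 0.811, for TCTP 0.699 and for Sod4A 0.613, while RPL27A had -0.0653 and tua4 -0.0627. Probes more than 2000 probe numbers apart had a median of 0.562. Probe number only stands in for slide position, so this argues against nearness in number and does not settle position. Removal of the trend with the approximated signal strength left a median of 0.550 over 63 genes. That is 97.6% of the value over the 72 genes, a different set. It cannot decide on the true signal strength either. Differences between single plants or harvests remain a candidate explanation, which was not tested.

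Arrays turned at random gave as many probes at an unadjusted p under 0.05 as the 123 of the F test over the 6 pairs in 39 of 100 groupings, the real one included here and below, with up to 397. For plots 2 and 3, 82 of 100 gave at least the observed 76, with up to 343; for plots 4 and 5, 11 of 100 gave at least 129, with up to 229; for plots 6 and 9, 46 of 100 gave at least 117, with up to 351. Subplots permuted within pairs gave at least the observed 40 in 82 of 100, with up to 189. Chance was therefore not excluded for these counts, and regroupings with several times the count point to structure shared by many probes. The splits were too few for plots 7 and 10 (16 observed, highest other 83, 8 of 8 splits as large), plots 11 and 12 (135, highest other 169, 2 of 8) and plots 13 and 15 (79, highest other 78, 1 of 4). With the ratios as deposited and no block, no other grouping of 100 reached the 11 calls of plots 2 and 3 or the 18 of the F test: 1 of 100 was as large in each, and the highest other was 1. With arrays of a shared plant code turned together, 1 of 100 groupings again reached the 18, with 2 as the highest other. Plots 2 and 3 then leave too few splits (11 observed, highest other 0, 1 of 2). Random turning does not tell a dye effect on single probes from a plot difference, and the fit as deposited had no dye term. Leaving out 1 array at a time moved the 18 to between 5 and 51.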

How the results depend on the processing

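The settings without both turning and block, those of shared plant codes, the list count and Fisher's tests as deposited, and those of gene-group means and of values per array, were chosen after seeing the data. Of 160 settings of the 11 probe counts, apart from single arrays left out, 141 gave the same count of 0. As deposited, with no dye term, the calls were 56 over the 6 pairs, 95 in plots 2 and 3, 44 in plots 11 and 12, 5 in plots 13 and 15 and 8 for August against June. Without the block as well they were 18, 11, 14, 1 and 0, and with a block for shared plant codes 54, 102, 44, 5 and 8. That block left all counts with turned ratios at 0. In plots 11 and 12, 29 probes passed among the 104 measured on all arrays and 31 with no dye term. With no filter 4 probes had a dye effect, July arrays alone gave 6 calls in plots 4 and 5, and the array with 1 plant code gave 1 call over the 4 times. The causes were not tested.

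With each array left out in turn, the counts ranged from 0 to 10 over the 6 pairs, 0 to 4 in plots 4 and 5, 0 to 76 in plots 11 and 12, 0 to 1 in plots 13 and 15 and 0 to 1 for August against June, and stayed at 0 for the other counts. Without replicate 4 of plots 11 and 12, an August array, there were 76 calls in that pair and 10 over the pairs. Replicate 5 of plots 4 and 5 gave 4 when left out, replicate 4 of plots 2 and 3 gave 1 in plots 4 and 5, replicate 2 of plots 7 and 10 gave 1 in plots 13 and 15, and replicate 2 of plots 11 and 12 gave 1 for August against June.

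The hsp70 mean of plots 4 and 5 stayed between 0.38 and 0.59 under all its settings and on the same side of the exact test, except with arrays of a shared plant code averaged (0.42, exact p = 0.125), where 4 sets allow no smaller p. The list passed in 1 pair with the preset correlation, in 0 with the estimated correlation, in 2 with arrays scaled alike and in 3 with the ratios as deposited, or 0 as deposited with the estimated correlation. Fry was not run, since 1 member was measured on all arrays. The mean correlation between pairs moved from 0.103 to 0.00490 with no dye term, 0.197 with June arrays and 0.155 with August arrays. The p for spread by time and by subplot and for values per array kept its side of the threshold under every setting run. Of 240 settings of the 40 named probes, 2 passed, both as deposited with the block: MNB1b probe 12499 over the pairs and LOC541649 probe 2093 for August against June. Signal over background was not used here, so its limit is unknown.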

Other observations

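In plots 7 and 10, both August arrays had a high hsp70 mean as deposited, 0.86 and 0.89, although the plots were in opposite channels, while the June arrays had -0.17 and -0.09. In plots 13 and 15 the MNB1b mean was 0.56 ± 0.08 (SD, n = 3), positive on 3 of 3 arrays, where the smallest exact permutation p is 0.25. In plots 11 and 12, TCTP was positive on 4 of 4 arrays, at 0.43 ± 0.19 (SD, n = 4), where the smallest exact p is 0.125. Joined by shared plant codes, the arrays form 2 sets in plots 13 and 15 and 2 in plots 11 and 12. The smallest exact sign-flip p is then 0.5 in each pair.

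The array labelled with 1 plant code in both channels gave values for 13515 probes, with a median of -0.40. Of these, 46.6% exceeded 1 in size, against 4.35% to 22.2% on the other arrays. Its MNB1b mean was 0.38 with an SD of 0.42 over 228 probes, and its hsp70-4 mean was -0.74 with an SD of 1.85 over 12 probes. Its correlation with the other arrays ran from -0.10 to 0.13 across probes.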
